A study of Homo sapiens with 16 samples.

How the data were processed

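RNA of Be(2)-C and IMR5-75 cells was sequenced in 16 libraries, 2 for each of the 8 groups of cell line and treatment (DMSO, DAC, EPZ-6438, both). Per the labels, total RNA was depleted of ribosomal RNA, libraries came from a strand-specific kit, and reads were single-end. The deposited table holds raw counts, which the authors made per gene symbol for each library, and their notes name TopHat2 2.0.5, HTSeq 0.5.3p9, DESeq2 without a version, and the genome build hg19. The gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes are uncertain. Near-identical genes such as histone, MAGEA, PAGE and protocadherin copies can exchange reads. All 16 count columns were mapped to a sample by line, treatment and replicate number. Levels of XIST and Y-linked genes were not used here, and some genes that the naming rule selects are not reported here.

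The table held 23459 genes, 1191 of them with 0 counts in every library. Library totals ran from 9539557 to 14032155, genes with a count from 17952 to 19480, TMM factors from 0.9276 to 1.116, and the share of the 10 most abundant genes from 6.153 to 8.638%. A floor of 3 counts corresponded to 0.206 to 0.315 CPM per library. Folds against a group with 0 counts are lower bounds against 3 counts over the group, and with 1 to 3 counts a ratio is given with its exact binomial 95% interval.

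Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (15967 tested), libraries scaled by TMM, and a quasi-likelihood model fitted to the 8 groups with 8 residual degrees of freedom (common biological variation 9.88%). Tests covered each treatment against DMSO in each line, both drugs against each alone, the interaction of the drugs in each line, and the difference of each treatment's change between lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, except where another origin is stated.

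The rule named, for each treatment against DMSO, the 5 highest and 5 lowest changes among called genes with a mean log2 CPM of at least 1 and both treated libraries on the same side of both DMSO libraries. It added, for each list with at least 3 called members, the 2 called members with the smallest adjusted p, and always DNMT1, DNMT3A, DNMT3B, EZH1, EZH2 and MYCN. In each other comparison it named the 4 highest and 4 lowest changes among called genes of that level.

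Of 27 gene lists written from general knowledge, 26 could be tested, since no mitochondrially encoded gene is in the table, and 3 members were matched under another name. They covered cancer-testis, germline, interferon-stimulated, antigen presentation, p53 target, mitosis, DNA replication, replication-dependent histone, HOX, imprinted, clustered protocadherin, cholesterol synthesis, ribosomal protein, and MYC and MYCN target genes. They also covered Polycomb-bound developmental regulators, EZH2-repressed neuroblastoma suppressors, genes methylated in neuroblastoma, noradrenergic identity, mesenchymal-type and neuronal maturation genes, DNA methylation and Polycomb machinery, and ATF4 and unfolded protein response genes. The last were Schwann and glial, epithelial and haematopoietic markers and small structured and nuclear RNAs. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Members were also adjusted over the list alone.

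The alternatives were DESeq2 size factors, no filter beyond genes with 0 counts in every library, the DESeq2 1.42.0 Wald test, a term for the replicate number, each line fitted alone, and each library left out in turn. Lists were also tested with an estimated correlation and with fry. Leaving out libraries for the lists was chosen after seeing the data. A lone library is then assumed to vary like the other groups. The methods were tested on simulated data with 200 changed genes per comparison. In these, edgeR recovered 22.4 to 44% of genes changed 1.5-fold, 57.1 to 80% of those changed 2-fold and 76 to 98% of those changed 4-fold, with 5.1 to 8.5% false calls. Camera called a simulated list of 40 genes raised 1.5-fold (adjusted p = 1.33e-30) and 0 of 50 unchanged lists. The simulated genes varied independently of each other, so this does not test false calls of lists whose members vary together. Gene neighbours were taken from a RefSeq table of another assembly, GRCh38.p14, for order only.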

Results

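RNA of IMR5-75 and of Be(2)-C, both human neuroblastoma lines, was sequenced. Neuroblastoma is a childhood tumour of the sympathetic nervous lineage, and both lines are widely used models that carry extra copies of MYCN, a transcription factor gene of the MYC family. Cells received DAC at 1 µM for 72 h, EPZ-6438 (EPZ below) at 1 µM for 96 h, both drugs, or the solvent DMSO. The labels do not spell out DAC, which usually stands for decitabine, a nucleoside that traps DNA methyltransferases. EPZ-6438 inhibits EZH2, the histone methyltransferase of a Polycomb repressive complex. Each of the 8 groups held 2 libraries, named by line, treatment and replicate (Be(2)-C DMSO 1). The 16 libraries held between 9539557 and 14032155 counts, and 15967 of 23459 genes were tested. No label says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Intervals and floors below cover counting error only. A bound against a group at 0 fell to between 0.466 and 0.534 of its value without either library of that group. Levels are counts scaled to library size (CPM), mean ± SD (n = 2), and changes are log2 ± SE against same-line DMSO unless stated. A gene list is named with its called members, and its median sets genes without counts in a group at their bound.

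**Figure D1:**
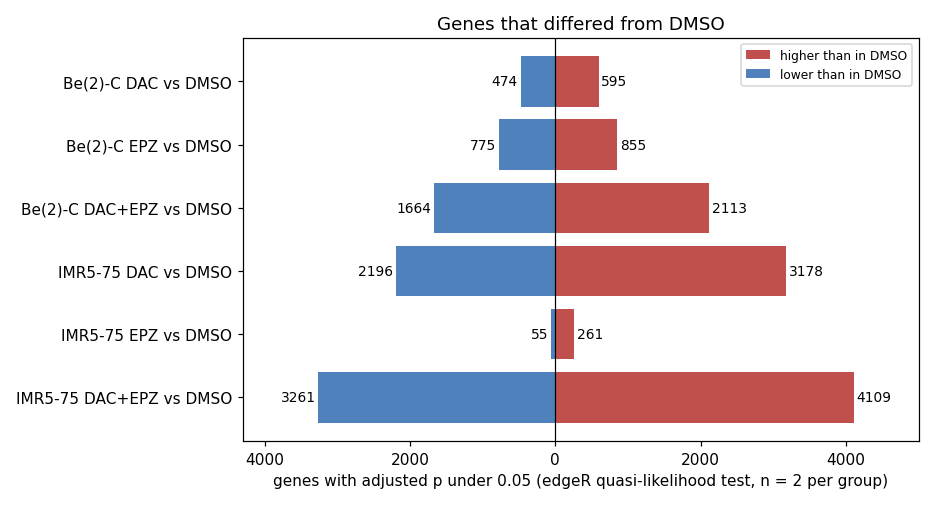
Number of genes that passed the edgeR test (adjusted p under 0.05, n = 2 libraries per group) in each treatment against DMSO of the same line, higher to the right and lower to the left. The bars run from 316 genes after EPZ in IMR5-75 to 7370 after both drugs in IMR5-75.

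The question of the DAC comparison in Be(2)-C was which genes changed when only DAC was given. Some germline and cancer-testis genes, which are expressed in germ cells and are silent in most other tissues, rose from almost no counts. DAZL, an RNA-binding protein gene of germ cells, had 12.4 ± 2.53 CPM after DAC against 1 count over the DMSO group (ratio 275, counting interval 49.0 to 10900, and at least 46.2-fold higher without DMSO 2). MAEL was at least 36.9-fold higher, PAGE5 at least 32.2-fold higher and MAGEA11 at least 27.7-fold higher, each with 0 counts in DMSO. H19, an imprinted noncoding RNA, rose by 6.03 ± 0.21, from 1.82 ± 0.499 to 120 ± 2.60 CPM (adjusted p = 5.75e-14). Replication-dependent histone genes, which are used in S phase, fell together, among them HIST1H3J by 1.58 ± 0.18 (282 ± 12.9 to 94.5 ± 5.57 CPM) and HIST1H4I by 1.45 ± 0.16.

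After DAC in Be(2)-C, 21 of 28 tested cancer-testis genes rose (median 4.13, adjusted p = 5.92e-29). So did 12 of 33 germline genes (median 1.68, adjusted p = 3.74e-12). Adjusted over the list alone, 22 and 14 rose. Of 57 histone genes 50 fell and 2 rose (53 and 2 adjusted over the list alone; median -0.98, adjusted p = 1.33e-50). The 2 that rose were HIST1H4F (ratio 177, interval 48.7 to 1470) and HIST1H1A (5.29 ± 0.46, and without DMSO 1 a ratio of 82.1, interval 14.5 to 3260), and near-identical histone copies can share reads. DNA replication genes fell in 30 of 44 cases (36 adjusted over the list alone; median -0.49, adjusted p = 4.86e-29), with PCNA, the sliding clamp of DNA polymerase, falling by 0.69 ± 0.11 (312 ± 8.92 to 194 ± 20.8 CPM). Mitosis genes fell in 16 of 40 cases (28 adjusted over the list alone; median -0.41, adjusted p = 4.73e-18), with BIRC5, or survivin, falling by 0.69 ± 0.11. Cholesterol synthesis genes fell in 15 of 25 cases (16 lower and 1 higher adjusted over the list alone; median -0.47, adjusted p = 3.28e-12), with ACAT2, an early enzyme of the pathway, falling by 0.73 ± 0.12.

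Further lists were called after DAC in Be(2)-C. Imprinted genes gave 7 higher and 1 lower of 28 (12 and 3 adjusted over the list alone; median 0.40, adjusted p = 4.45e-05), and MKRN3 rose by 3.77 ± 0.36. Epithelial markers gave 3 higher of 7 (4 adjusted over the list alone; median 1.45, adjusted p = 0.000107). MYC and MYCN target genes gave 1 higher and 6 lower of 40 (1 and 11 adjusted over the list alone; median -0.23, adjusted p = 1.09e-07), and the higher gene was LDHA, lactate dehydrogenase A, at 78.4 ± 1.02 against 37.8 ± 1.51 CPM. Clustered protocadherin genes, cell-surface proteins of neurons, gave 12 higher of 52 (13 adjusted over the list alone; median 0.41, adjusted p = 7.76e-09), and the call was lost at adjusted p = 0.0724 with an estimated correlation. Mesenchymal-type genes gave 8 higher and 1 lower of 40 (9 and 2 adjusted over the list alone; median 0.22, adjusted p = 0.00958 and adjusted p = 0.059 with an estimated correlation). FN1, fibronectin, rose by 1.18 ± 0.17 among them. Ribosomal protein genes gave 1 lower of 74 (0 adjusted over the list alone; median -0.07, adjusted p = 0.0168 and adjusted p = 0.66 with an estimated correlation). The other lists were not called, at adjusted p between 0.0528 and 0.629, among them interferon-stimulated genes (adjusted p = 0.0528) and p53 target genes (adjusted p = 0.109).

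In all, 1069 genes passed after DAC in Be(2)-C, 595 higher and 474 lower. The count was 297 (189 higher) without DMSO 1, 379 (226 higher) without DMSO 2, 444 (294 higher) without DAC 1 and 583 (357 higher) without DAC 2. Without these libraries in the same order, the DNA replication genes lower numbered 9, 10, 16 and 11 and the mitosis genes lower 4, 5, 10 and 3. Without DMSO 1, DMSO 2 and DAC 1, the cholesterol synthesis genes lower numbered 7 each, the clustered protocadherin genes higher 3, 5 and 7, and the MYC and MYCN target genes lower 1, 3 and 1. The replication-dependent histone genes lower numbered 32 without DAC 1, the imprinted genes higher 4 without DMSO 1, and the mesenchymal-type genes higher 3 without DMSO 1 or DMSO 2. The epithelial markers higher numbered 1 without DMSO 1 or DMSO 2. The call of the mesenchymal-type genes ended without DMSO 2 (adjusted p = 0.0568), and that of the ribosomal protein genes without DMSO 1 (adjusted p = 0.191) or DAC 1 (adjusted p = 0.55).

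EPZ alone in Be(2)-C lowered genes of cell division. NUSAP1, a spindle protein, fell by 1.03 ± 0.11 (312 ± 4.80 to 152 ± 2.18 CPM), KIF20A, a mitotic kinesin, by 0.92 ± 0.11, and CHAF1B, a chromatin assembly factor subunit, by 1.25 ± 0.13. EZH2 itself fell by 0.58 ± 0.11 (98.2 ± 1.09 to 65.9 ± 4.52 CPM), and its partner PHF19 fell by 0.84 ± 0.13. Higher genes included SEL1L3 (4.45 ± 0.37, 0.274 ± 0.00252 to 6.19 ± 0.278 CPM), the antigen-presenting HLA-C (1.11 ± 0.17) and HLA-E (1.97 ± 0.31, and 2.56 without DMSO 2), FN1 (1.37 ± 0.17), and the neuronal gene DCX (1.10 ± 0.17). SLC7A11, a cystine transporter, rose by 1.47 ± 0.24, from 30.8 ± 6.54 to 85.5 ± 6.75 CPM.

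After EPZ in Be(2)-C, 41 of 44 DNA replication genes fell (median -0.80, adjusted p = 1.58e-48), as did 35 of 40 mitosis genes (median -0.70, adjusted p = 1.31e-38) and 51 of 57 replication-dependent histone genes (median -0.99, adjusted p = 6.66e-53). Adjusted over the list alone, 42, 38 and 54 fell. MYC and MYCN target genes gave 6 lower of 40 (13 adjusted over the list alone; median -0.24, adjusted p = 1.38e-08) and cholesterol synthesis genes 9 lower of 25 (9 adjusted over the list alone; median -0.27, adjusted p = 1.88e-07). Calls lost with an estimated correlation were antigen presentation genes (4 higher of 16, 5 higher and 1 lower adjusted over the list alone; median 0.32, adjusted p = 0.238 with an estimated correlation) and mesenchymal-type genes (10 higher and 2 lower of 40, 13 and 3 adjusted over the list alone; median 0.43, adjusted p = 0.0625 with an estimated correlation). The same held for neuronal maturation genes (8 higher of 43, 9 adjusted over the list alone; median 0.19, adjusted p = 0.241 with an estimated correlation) and clustered protocadherin genes (3 higher, 0 adjusted over the list alone; median 0.45, adjusted p = 0.238 with an estimated correlation). It also held for ATF4 and unfolded protein response genes (5 higher and 1 lower of 30, 8 and 1 adjusted over the list alone; median 0.26, adjusted p = 0.419 with an estimated correlation) and ribosomal protein genes (0 called; median -0.10, adjusted p = 0.708 with an estimated correlation). No cancer-testis or germline gene passed after EPZ in Be(2)-C.

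EPZ changed 1630 genes in Be(2)-C, 855 higher and 775 lower, and the count was 571 (291 higher) without DMSO 1 and 672 (351 higher) without DMSO 2, and the lower genes numbered 488 without EPZ 2. Without DMSO 1 and DMSO 2, the mesenchymal-type genes higher numbered 3 each, the cholesterol synthesis genes lower 3 each, the MYC and MYCN target genes lower 1 and 2, and the neuronal maturation genes higher 5 and 4. Without EPZ 1 the last 3 numbered 5, 3 and 5, and the MYC and MYCN target genes lower numbered 3 without EPZ 2. The clustered protocadherin genes higher numbered 0 without DMSO 1, DMSO 2 or EPZ 1 and 2 without EPZ 2. The ATF4 and unfolded protein response genes higher numbered 3 without DMSO 1 and 9 without EPZ 2, and the ribosomal protein genes lower 4 without EPZ 1. Without EPZ 1 the calls of the neuronal maturation genes (adjusted p = 0.418), the ATF4 and unfolded protein response genes (adjusted p = 0.149) and the antigen presentation genes (adjusted p = 0.0611) ended, and the last also ended without DMSO 2 (adjusted p = 0.0862).

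Both drugs together in Be(2)-C raised FN1 from 10.2 ± 0.487 to 92.9 ± 12 CPM (3.19 ± 0.16, adjusted p = 3.52e-11) and SPARC, another matrix protein gene, by 1.85 ± 0.12. The neurotrophin receptor gene NTRK3 rose (3.95 ± 0.45, and without DMSO 1 a ratio of 27.8, interval 7.51 to 233), as did CHGB, a secretory granule protein gene (1.30 ± 0.13). PAGE5 was at least 47.2-fold higher, DAZL had a ratio of 192 (interval 34.1 to 7630, and at least 32.2-fold higher without DMSO 2) and MAGEA12 of 57.5 (interval 15.6 to 481). UHRF1, which guides DNMT1 to newly copied DNA, fell by 1.46 ± 0.11 (210 ± 1.42 to 76.4 ± 6.85 CPM), CCNA2, or cyclin A, by 1.36 ± 0.12, and HIST1H2BI by 1.86 ± 0.13. WT1, a developmental transcription factor gene, fell to a ratio of 0.0598 (interval 0.0119 to 0.184, and 0.0368, interval 0.000915 to 0.214, without DAC+EPZ 2). GDF15, a stress-induced secreted factor, fell by 3.58 ± 0.66 (by 2.97 without DMSO 2).

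Under both drugs in Be(2)-C, 23 of 28 cancer-testis genes rose (median 3.30, adjusted p = 1.21e-16), 17 of 33 germline genes (median 2.83, adjusted p = 1.13e-06) and 5 of 7 epithelial markers, led by KRT8 (median 1.86, adjusted p = 0.00188). Adjusted over the list alone, 25, 19 and 5 rose. DNA replication genes fell in 43 of 44 cases (median -1.07, adjusted p = 9.21e-46), mitosis genes in 37 of 40 (median -0.85, adjusted p = 1.03e-31) and histone genes in 54 of 57, with 2 higher (median -1.49, adjusted p = 7.81e-48). Adjusted over the list alone, 43, 39 and 54 fell. Mesenchymal-type genes gave 19 higher and 2 lower (20 and 2 adjusted over the list alone; median 0.97, adjusted p = 2.19e-07) and interferon-stimulated genes 9 higher and 1 lower of 36 (11 and 1 adjusted over the list alone; median 0.45, adjusted p = 0.0125), with BST2, or tetherin, rising by 2.46 ± 0.37. MYC and MYCN target genes gave 29 lower and 1 higher (30 and 1 adjusted over the list alone; median -0.40, adjusted p = 5.26e-13). Cholesterol synthesis genes gave 15 lower and 1 higher (17 and 2 adjusted over the list alone; median -0.51, adjusted p = 1.06e-08) and imprinted genes 13 higher and 1 lower (13 and 1 adjusted over the list alone; median 0.60, adjusted p = 0.00131).

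Calls lost with an estimated correlation under both drugs in Be(2)-C were those of clustered protocadherin genes (21 higher, 23 adjusted over the list alone; median 0.62, adjusted p = 0.0742 with an estimated correlation) and neuronal maturation genes (16 higher, 17 adjusted over the list alone; median 0.24, adjusted p = 0.0899 with an estimated correlation). Antigen presentation genes (5 higher, 6 adjusted over the list alone; median 0.29, adjusted p = 0.0973 with an estimated correlation) and ATF4 and unfolded protein response genes (1 higher and 13 lower, 1 and 14 adjusted over the list alone; median -0.37, adjusted p = 0.286 with an estimated correlation) also lost theirs. The lower members of that list included the amino acid transporter genes SLC7A5, which fell by 1.02 ± 0.17, and SLC3A2, which fell by 0.84 ± 0.13. In all, 3777 genes passed, 2113 higher and 1664 lower, against 2100 (1147 higher) without DMSO 1, 2199 (1245 higher) without DMSO 2 and 2241 (1323 higher) without DAC+EPZ 2. Without DMSO 1, DMSO 2, DAC+EPZ 1 and DAC+EPZ 2 the MYC and MYCN target genes lower numbered 14, 14, 18 and 13. Without DMSO 2, DAC+EPZ 1 and DAC+EPZ 2 the ATF4 and unfolded protein response genes lower numbered 8, 7 and 8. Without DMSO 2 the germline genes higher numbered 11, the neuronal maturation genes 10, the antigen presentation genes 3 and the epithelial markers 3, and without DMSO 1 the interferon-stimulated genes numbered 5, the clustered protocadherin genes 11 and the imprinted genes 8. Without DAC+EPZ 2 the clustered protocadherin genes higher numbered 13, the imprinted genes 7, the neuronal maturation genes 10 and the antigen presentation genes 3.

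The comparison of both drugs with each alone asked what the added drug changed in Be(2)-C. Against EPZ alone, MAGEA12 was at least 38.2-fold higher, HIST1H4F at least 37.5-fold higher and MAEL at least 35.0-fold higher under both drugs. HMOX1, or heme oxygenase, fell by 4.02 ± 0.36 (33.6 ± 6.09 to 2.03 ± 0.651 CPM), GDF15 by 5.42 ± 0.55, INHBE by 3.49 ± 0.35 and FAM129A by 3.96 ± 0.50 (by 3.28 without DAC+EPZ 2, and without DAC+EPZ 1 a ratio of 0.0171, interval 0.000429 to 0.0968). Against DAC alone, F2R, a thrombin receptor gene, was higher at a ratio of 14.7 (interval 4.69 to 74.5, and 23.4, interval 3.97 to 948, without DAC 2). There GDF15 fell by 3.85 ± 0.64 (by 4.44 without DAC 1 and 2.93 without DAC 2) and INHBE fell by 2.85 ± 0.36 (by 2.16 without DAC 2). Of 672 genes that passed against EPZ, 454 were higher and 218 lower, and the count was 331 (256 higher) without DAC+EPZ 1, 283 (214 higher) without DAC+EPZ 2 and 353 (218 higher) without EPZ 2. Of 869 genes against DAC, 546 were higher and 323 lower, and the count was 412 (261 higher) without DAC 1, 370 (221 higher) without DAC 2, 443 (296 higher) without DAC+EPZ 1 and 323 (218 higher) without DAC+EPZ 2.

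The interaction asked whether the change under both drugs differed from the sum of the single-drug changes. In Be(2)-C, 41 genes passed, 39 of them below the sum. INHBE, an activin subunit gene, lay below it by -4.99 ± 0.46 (adjusted p = 4.63e-06), HMOX1 by -4.60 ± 0.48 (adjusted p = 2.53e-05), GDF15 by -5.69 ± 0.72 (adjusted p = 0.000232) and FAM129A by -4.82 ± 0.69 (adjusted p = 0.000892). Without DAC 2 the values were -4.30 for INHBE, -3.77 for HMOX1 and -4.77 for GDF15, which stood at -6.30 without DMSO 2, and FAM129A stood at -4.14 without DAC+EPZ 2 and had 1 count left under both drugs without DAC+EPZ 1. INHBE stood at 16.3 ± 0.609 CPM after EPZ, 10.6 ± 5.75 after DAC and 1.45 ± 0.168 after both. The 2 genes above the sum were DBI (0.96 ± 0.20) and DCN (0.96 ± 0.20), and their calls ended without DMSO 1, DMSO 2, DAC 1, DAC 2, DAC+EPZ 1 or EPZ 2, and for DCN also without EPZ 1, at adjusted p up to 0.338 and 0.395. The count was 16 without DMSO 1, 18 without DAC 2, 24 without DAC+EPZ 1 and 26 without DAC+EPZ 2, and the genes above the sum numbered 20 without EPZ 1.

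**Figure D2:**
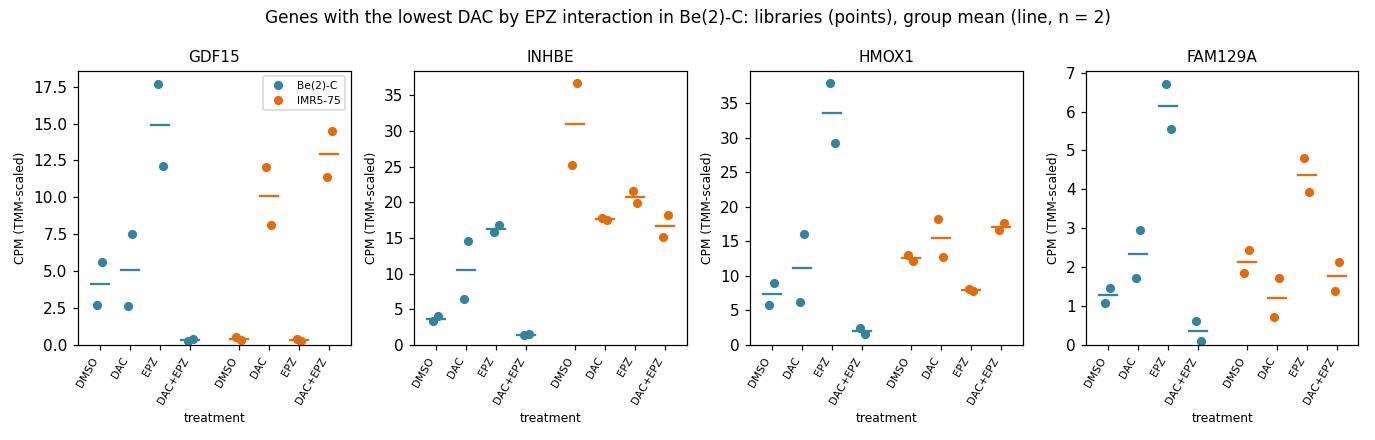
Level of GDF15, INHBE, HMOX1 and FAM129A (CPM) in each library of the 4 treatments of both lines, with group means (n = 2). In Be(2)-C, HMOX1 stood at 33.6 CPM after EPZ and at 2.03 CPM after both drugs.

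DAC alone in IMR5-75 raised genes of many kinds. DAZL reached 121 ± 17.7 CPM against 1 count in DMSO (ratio 3052, interval 547 to 121000, and at least 475-fold higher without DMSO 1), MAGEA4, a cancer-testis antigen, was at least 232-fold higher, and HIST1H2BA, a testis histone, at least 248-fold higher. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 99.8 ± 7.57 to 641 ± 63.8 CPM (2.68 ± 0.15, adjusted p = 2.58e-11). PRPH, the neuronal filament peripherin, rose from 18.5 ± 1.11 to 172 ± 28.3 CPM, and SCG2, a secretory granule protein, by 3.20 ± 0.19. COL3A1, a fibrillar collagen gene, rose by 2.07 ± 0.15. TERT, the telomerase subunit, fell by 3.04 ± 0.39, and LDHA fell by 1.35 ± 0.10 (1250 ± 16.1 to 490 ± 19.8 CPM).

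All 28 tested cancer-testis genes rose after DAC in IMR5-75 (median 5.79, adjusted p = 2.12e-22), as did 27 of 33 germline genes (median 4.42, adjusted p = 3.71e-16) and 50 of 52 clustered protocadherin genes (median 3.46, adjusted p = 1.8e-20). Adjusted over the list alone, 28, 28 and 50 rose. Of 36 p53 target genes 31 rose (31 adjusted over the list alone; median 1.24, adjusted p = 3.28e-20), with BTG2, an antiproliferative gene, at 1.88 ± 0.11. Interferon-stimulated genes gave 24 higher and 1 lower (25 and 2 adjusted over the list alone; median 1.34, adjusted p = 2.4e-06), with HERC5 at 1.99 ± 0.17 and PARP14 at 3.77 ± 0.41. Genes methylated in neuroblastoma gave 18 higher and 2 lower of 26 (19 and 2 adjusted over the list alone; median 1.67, adjusted p = 4.06e-06), among them the decoy receptor gene TNFRSF10D, with 6 counts in DMSO 1 and 0 in DMSO 2 (6.97 ± 0.39, and 6.08 without DMSO 2). The 3 tested EZH2-repressed neuroblastoma suppressors all rose (3 adjusted over the list alone; median 1.78, adjusted p = 0.00251), among them CLU (1.78 ± 0.17) and NGFR (1.91 ± 0.29, 1.28 without DMSO 1 and 2.91 without DMSO 2). Neuronal maturation genes gave 26 higher and 5 lower (28 and 5 adjusted over the list alone; median 0.91, adjusted p = 7.89e-07) and mesenchymal-type genes 24 higher (27 adjusted over the list alone; median 0.95, adjusted p = 6.14e-08). Imprinted genes gave 16 higher and 1 lower (18 and 1 adjusted over the list alone; median 1.14, adjusted p = 5.64e-05) and Schwann and glial markers 6 higher of 9 (6 adjusted over the list alone; median 2.14, adjusted p = 0.00203).

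Genes of cell division fell after DAC in IMR5-75: 39 of 40 mitosis genes (median -0.77, adjusted p = 3.16e-25), all 44 DNA replication genes (median -0.71, adjusted p = 1.92e-26) and 28 MYC and MYCN target genes (median -0.45, adjusted p = 4.02e-13). Numbers adjusted over the list alone were 40, 44 and 31. KIF15, a mitotic kinesin, fell by 1.13 ± 0.13 and UHRF1 by 1.00 ± 0.11. The histone genes split, with 19 higher and 34 lower (20 and 34 adjusted over the list alone). Their median was -0.996, their mean 1.20 and their test pointed down (adjusted p = 0.000579), and the call was lost at adjusted p = 0.517 with an estimated correlation. Their summed level fell to 45.1% of DMSO (16140 ± 4470 to 7282 ± 1210 CPM). HIST1H1B, a linker histone gene, rose from 1 count to 31.8 ± 3.18 CPM (ratio 812, interval 145 to 32100, and at least 126-fold higher without DMSO 1). Other calls lost with an estimated correlation were those of antigen presentation genes (8 higher, 8 adjusted over the list alone; median 0.80, adjusted p = 0.0924 with an estimated correlation) and noradrenergic identity genes (14 higher and 3 lower of 30, 14 and 3 adjusted over the list alone; median 0.49, adjusted p = 0.237 with an estimated correlation). DNA methylation and Polycomb machinery gave 11 lower of 38 (11 adjusted over the list alone; median -0.20, adjusted p = 0.0697 with an estimated correlation). Cholesterol synthesis genes (3 higher and 10 lower, 3 and 10 adjusted over the list alone; median -0.29 but mean 0.03, adjusted p = 0.237 with an estimated correlation) and ribosomal protein genes (2 lower, 0 adjusted over the list alone; median -0.10, adjusted p = 0.615 with an estimated correlation) did so too.

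HOX genes, Polycomb-bound developmental regulators, epithelial markers, haematopoietic markers, ATF4 and unfolded protein response genes and small structured and nuclear RNAs were not called after DAC in IMR5-75, at adjusted p = 0.181, 0.333, 0.121, 0.15, 0.131 and 0.407. In all, 5374 genes passed, 3178 higher and 2196 lower, and the lower genes numbered 1463 without DMSO 1. Without DMSO 2 the cholesterol synthesis genes lower numbered 4, the antigen presentation genes higher 4 and the imprinted genes higher 10. The DNA methylation and Polycomb machinery genes lower numbered 6 without DMSO 1 and 7 without DAC 1, and the neuronal maturation genes lower 2, 3 and 3 without DMSO 1, DAC 1 and DAC 2. The cholesterol synthesis call ended without DMSO 2, DAC 1 or DAC 2 (adjusted p = 0.202, 0.0779 and 0.0531), and the ribosomal protein genes call without DMSO 2 or DAC 2 (adjusted p = 0.244 and 0.18).

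**Figure D3:**
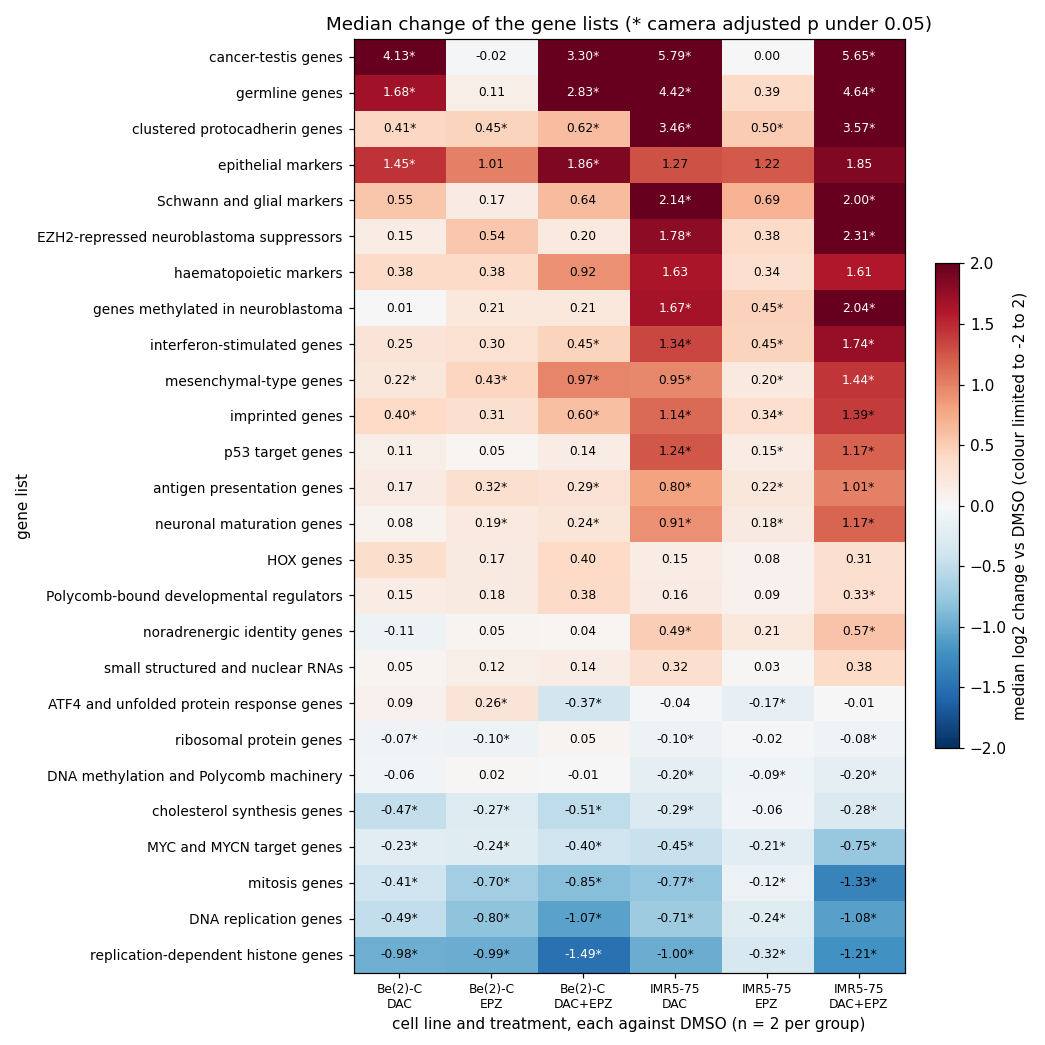
Median log2 change of the 26 tested gene lists (vertical) in the 6 treatments against DMSO (horizontal, n = 2 libraries per group), with genes without counts in a group at their bound and an asterisk where camera gave an adjusted p under 0.05. Cancer-testis genes reached medians of 4.13, 3.30, 5.79 and 5.65 in the treatments with DAC.

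EPZ alone changed few genes in IMR5-75. FOS, an immediate early transcription factor gene, rose by 2.81 ± 0.34 (3.49 ± 1.60 to 24.2 ± 3.08 CPM, adjusted p = 0.00021), PRPH by 1.34 ± 0.17 (18.5 ± 1.11 to 46.8 ± 3.52 CPM, adjusted p = 0.000239) and the p53 target TP53I3 by 0.79 ± 0.12 (59.4 ± 2.69 to 102 ± 4.94 CPM, adjusted p = 0.000953). These were the 3 genes named by the rule whose calls stood with each library left out in turn. DNA replication genes had a median of -0.24 with 5 lower (20 adjusted over the list alone; adjusted p = 9.03e-16), MYC and MYCN target genes -0.21 with 2 lower (4 adjusted over the list alone; adjusted p = 1.52e-12). The p53 target genes had a median of 0.15 with 6 higher (6 adjusted over the list alone; adjusted p = 0.00198) and interferon-stimulated genes 0.45 with 0 called (2 adjusted over the list alone; adjusted p = 0.00198). EZH2 differed by -0.15 and was not called (adjusted p = 0.486).

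Another 10 lists were called after EPZ in IMR5-75 and lost the call with an estimated correlation. The adjusted p with an estimated correlation was 0.287 for mitosis genes (0 called, 0 adjusted over the list alone), 0.52 for replication-dependent histone genes (1 lower, 0 adjusted over the list alone; median -0.32 but mean 0.30), 0.373 for ATF4 and unfolded protein response genes (2 lower, 3 adjusted over the list alone) and 0.231 for neuronal maturation genes (5 higher, 7 adjusted over the list alone). The adjusted p with an estimated correlation was 0.117 for mesenchymal-type genes (3 higher, 6 adjusted over the list alone), genes methylated in neuroblastoma (3 higher, 3 adjusted over the list alone) and imprinted genes (0 called), 0.231 for antigen presentation genes (1 higher, 3 adjusted over the list alone), 0.373 for clustered protocadherin genes (0 called) and 0.233 for DNA methylation and Polycomb machinery (0 called). In all 316 genes passed, 261 higher and 55 lower, against 2560 at an unadjusted p under 0.05.

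The count after EPZ in IMR5-75 was 32 without DMSO 2, 60 without EPZ 1 and 111 without EPZ 2, with 3, 2 and 2 lower, and the lower genes numbered 89 without DMSO 1. The number of lower genes thus depended on single libraries. Without these 3 libraries the DNA replication genes lower numbered 0, 0 and 0, the p53 target genes higher 2, 2 and 3, and the neuronal maturation genes higher 1, 2 and 1 (3 without DMSO 1), and the replication-dependent histone genes lower numbered 4 without DMSO 1. The genes methylated in neuroblastoma higher numbered 0, 0 and 0 without the same 3 libraries, and the mesenchymal-type genes higher 0 without DMSO 2 and 1 without EPZ 1. List calls that ended were those of antigen presentation genes without DMSO 2 or EPZ 1 (adjusted p = 0.0952 and 0.173), DNA methylation and Polycomb machinery without DMSO 1, DMSO 2 or EPZ 1 (0.0765, 0.107 and 0.125), and genes methylated in neuroblastoma without DMSO 1 or EPZ 1 (0.121 and 0.0895). Imprinted genes lost theirs without DMSO 2 (0.0914), mesenchymal-type genes without EPZ 1 (0.0895), and replication-dependent histone genes without DMSO 2 or EPZ 2 (0.717 and 0.0562).

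Both drugs in IMR5-75 gave the most calls of the 6 treatments. CDKN1A rose to 669 ± 64.0 CPM (2.75 ± 0.15), PRPH to 274 ± 33.8 CPM (3.89 ± 0.18) and COL3A1 to 419 ± 13.2 CPM from 53.4 ± 0.856 (2.97 ± 0.15). TGFBI, a matrix protein gene, went from 2 counts to 20.5 ± 1.15 CPM (ratio 260, interval 71.7 to 2150). NEFM, a neurofilament gene, rose by 2.65 ± 0.14 and MSX1, a homeobox gene, by 2.77 ± 0.20. KIF15 fell by 1.88 ± 0.13, MCM10, a replication initiation factor gene, by 1.46 ± 0.11, and MTHFD2, a mitochondrial folate enzyme gene, by 1.08 ± 0.12. Among the drug targets DNMT1 fell by 0.70 ± 0.13 (316 ± 17.5 to 195 ± 11.7 CPM) and EZH2 by 0.56 ± 0.10, and MYCN fell by 0.65 ± 0.14, from 1872 ± 181 to 1190 ± 0.605 CPM.

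Under both drugs in IMR5-75, 27 cancer-testis genes (median 5.65, adjusted p = 8.87e-17), 30 germline genes (median 4.64, adjusted p = 1.2e-13), 49 clustered protocadherin genes (median 3.57, adjusted p = 2.37e-15) and 26 p53 target genes (median 1.17, adjusted p = 2.48e-11) rose. The numbers adjusted over the list alone were 27, 30, 50 and 26. Interferon-stimulated genes gave 27 higher and 2 lower (28 and 2 adjusted over the list alone; median 1.74, adjusted p = 4.26e-07), mesenchymal-type genes 30 higher and 2 lower (30 and 3 adjusted over the list alone; median 1.44, adjusted p = 2.12e-09), and neuronal maturation genes 30 higher and 5 lower (31 and 5 adjusted over the list alone; median 1.17, adjusted p = 1.39e-07). Genes methylated in neuroblastoma gave 20 higher and 2 lower (21 and 2 adjusted over the list alone; median 2.04, adjusted p = 1.64e-06) and imprinted genes 17 higher and 1 lower (17 and 2 adjusted over the list alone; median 1.39, adjusted p = 2.09e-05). Schwann and glial markers gave 7 higher (7 adjusted over the list alone; median 2.00, adjusted p = 0.000478) and EZH2-repressed neuroblastoma suppressors 3 higher (3 adjusted over the list alone; median 2.31, adjusted p = 0.0019). All 40 mitosis genes (median -1.33, adjusted p = 9.04e-31), all 44 DNA replication genes (median -1.08, adjusted p = 6.5e-28) and 35 MYC and MYCN target genes (median -0.75, adjusted p = 2.37e-15) fell, with the same 3 counts adjusted over the list alone. DNA methylation and Polycomb machinery gave 3 higher and 16 lower (3 and 16 adjusted over the list alone; median -0.20, adjusted p = 0.00129).

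Lost with an estimated correlation under both drugs in IMR5-75 were the calls of replication-dependent histone genes (20 higher and 34 lower, 20 and 34 adjusted over the list alone; median -1.21 but mean 1.09, adjusted p = 0.486 with an estimated correlation) and antigen presentation genes (10 higher, 10 adjusted over the list alone; median 1.01, adjusted p = 0.0603 with an estimated correlation). Noradrenergic identity genes gave 15 higher and 5 lower (15 and 5 adjusted over the list alone; median 0.57, adjusted p = 0.259 with an estimated correlation). Polycomb-bound developmental regulators (19 higher and 4 lower, 19 and 4 adjusted over the list alone; median 0.33, adjusted p = 0.206 with an estimated correlation), cholesterol synthesis genes (4 higher and 11 lower, 4 and 12 adjusted over the list alone; median -0.28, adjusted p = 0.219 with an estimated correlation) and ribosomal protein genes (2 lower, 0 adjusted over the list alone; median -0.08, adjusted p = 0.708 with an estimated correlation) lost theirs too. In all 7370 genes passed, 4109 higher and 3261 lower. The DNA methylation and Polycomb machinery genes lower numbered 10 without DAC+EPZ 2, and those higher 1 without DMSO 1, DMSO 2 or DAC+EPZ 1. Without DMSO 2, DAC+EPZ 1 and DAC+EPZ 2, the neuronal maturation genes lower numbered 3, 2 and 2 and the noradrenergic identity genes lower 3, 3 and 3, and the Polycomb-bound developmental regulators lower 2 without DMSO 2 or DAC+EPZ 1. The cholesterol synthesis genes call ended without DMSO 2 or DAC+EPZ 1 (adjusted p = 0.123 and 0.0659), and the ribosomal protein genes call without either (adjusted p = 0.415 and 0.597).

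**Figure D4:**
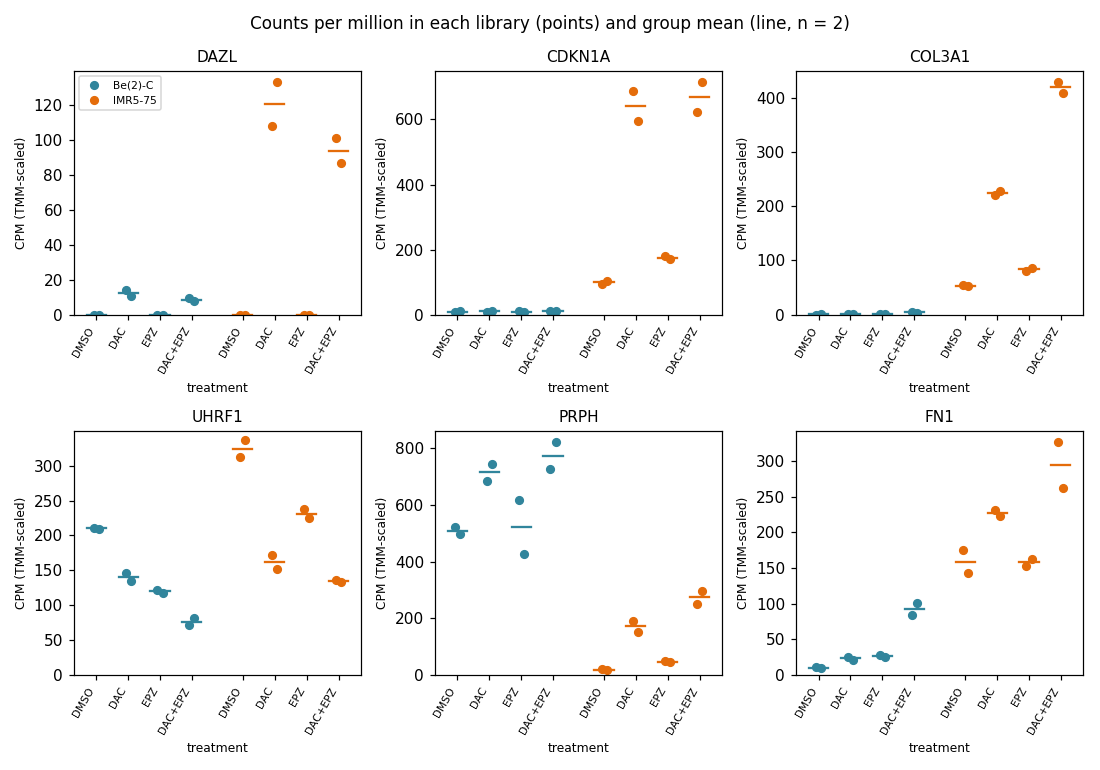
Level of DAZL, CDKN1A, COL3A1, UHRF1, PRPH and FN1 (CPM) in each of the 16 libraries, with group means (n = 2 per group). CDKN1A rose in IMR5-75 from 99.8 to 641 and 669 CPM in the treatments with DAC, and FN1 in Be(2)-C from 10.2 to 92.9 CPM under both drugs.

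Added to EPZ, DAC raised L1TD1, an RNA-binding protein gene of early embryos, at least 611-fold in IMR5-75 (72.2 ± 0.786 CPM under both drugs, 0 counts after EPZ) and MAGEA4 at least 298-fold. KRT19, an epithelial keratin gene, was at least 12.9-fold lower under both drugs than after EPZ, and at least 6.65-fold lower without EPZ 1. This comparison gave 6005 genes, 3307 higher and 2698 lower, and 3728 without EPZ 2. The lower genes numbered 1470 without DAC+EPZ 2, 1707 without EPZ 1 and 1391 without EPZ 2. Added to DAC, EPZ changed 309 genes in IMR5-75, 194 higher and 115 lower, against 52 (3 lower) without DAC 2, 74 (10 lower) without DAC+EPZ 1 and 48 (6 lower) without DAC+EPZ 2, so the balance of higher and lower genes did not hold. GREM1, a secreted BMP antagonist gene, was higher by 2.03 ± 0.38 (adjusted p = 0.00826, and 2.64 without DAC 2), and its call ended without DAC 1 or DAC+EPZ 1, at adjusted p up to 0.0948. FOS was lower by -1.27 ± 0.28 (adjusted p = 0.0207), and its call ended without DAC 2, DAC+EPZ 1 or DAC+EPZ 2, at adjusted p up to 0.338, and with DESeq2.

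The interaction in IMR5-75 gave 4 genes. FOS lay below the sum of the single-drug changes by -4.08 ± 0.44 (adjusted p = 0.000137), with 24.2 ± 3.08 CPM after EPZ, 36.9 ± 12 after DAC and 15.3 ± 3.96 after both. NEFM (1.29 ± 0.19, adjusted p = 0.0071) lay above the sum, and its call ended without EPZ 1 or EPZ 2, at adjusted p up to 0.0675. RGS4 (1.56 ± 0.25) lay above it until DMSO 2, DAC 1, EPZ 1 or EPZ 2 was left out, at adjusted p up to 0.351. ADCYAP1, a neuropeptide gene, lay below it (-1.64 ± 0.26) until DMSO 1, DMSO 2, DAC 1, DAC+EPZ 1 or EPZ 1 was left out, at adjusted p up to 0.258. NEFM, RGS4 and ADCYAP1 also lost their calls when IMR5-75 was fitted alone. The count was 10 without DMSO 1, 2 without DAC 1, 1 without EPZ 1 and 2 without EPZ 2.

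The remaining fixed genes moved little. In Be(2)-C, DNMT1 (-0.18, adjusted p = 0.437), EZH2 (-0.33, adjusted p = 0.0641) and MYCN (-0.35, adjusted p = 0.151) were not called after DAC. DNMT1 fell by 0.44 ± 0.13 after EPZ (adjusted p = 0.029), a call that ended without DMSO 1, DMSO 2 or EPZ 2, at adjusted p up to 0.297. Under both drugs in Be(2)-C, EZH2 fell by 0.72 ± 0.11 and DNMT1 fell by 0.53 ± 0.13, the latter not called without DAC+EPZ 1 (adjusted p = 0.0585). DNMT3A, a de novo methyltransferase gene, rose by 0.41 ± 0.10, a call that ended without DMSO 1 or DAC+EPZ 2, at adjusted p up to 0.0811. MYCN fell by 0.42 ± 0.14 (adjusted p = 0.0363), a call that ended without any of the 4 libraries compared, at adjusted p up to 0.149. After DAC in IMR5-75, DNMT1 fell by 0.45 ± 0.13, EZH2 by 0.35 ± 0.10 and MYCN by 0.52 ± 0.14. Those calls ended without DMSO 1 or DAC 2, without DMSO 1 or DAC 1, and without DMSO 2 or DAC 2, at adjusted p up to 0.0856, 0.111 and 0.113. EZH1 rose by 0.32 ± 0.12 under both drugs in IMR5-75, a call that ended without DMSO 1, DMSO 2 or DAC+EPZ 1, at adjusted p up to 0.157. DNMT3B was called in none of the 6 treatments.

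Calls overlapped between the lines, which share no library. After DAC 402 genes rose in both lines and 340 fell in both, against 118 and 65.2 expected of independent lists, and 44 were called in opposite directions against 176 expected. For EPZ 88 rose in both lines and 17 fell in both, against 14 and 2.67 expected. Under both drugs 1332 rose in both lines and 1285 fell in both, against 544 and 340 expected. Within Be(2)-C, the EPZ step without and with DAC, which share no library, gave 286 genes higher in both and 201 lower in both, against 29.2 and 15.7 expected. The DAC step without and with EPZ gave 237 and 72, against 16.9 and 6.47. In IMR5-75 the EPZ steps gave 61 and 4, against 3.17 and 0.396, and the DAC steps 2438 and 1578, against 658 and 371.

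The tests of the difference between lines asked which changes were larger in one line. After DAC, HIST1H1B differed by 10.48 ± 0.51, ZIK1, a zinc finger gene, by 9.49 ± 0.72 and C3orf14 by 9.19 ± 0.71, each with at most 1 count in IMR5-75 DMSO, so these are fitted values and no folds. After EPZ, FOS differed by 3.36 ± 0.45 and SEL1L3 by -3.50 ± 0.46 (IMR5-75 minus Be(2)-C), and under both drugs PDGFRA, a growth factor receptor gene, by -5.87 ± 0.28. The counts were 988 genes for DAC, 819 of them more positive in IMR5-75, 190 for EPZ, 91 and 99 in each direction, and 1766 for both drugs, 1071 more positive in IMR5-75. The EPZ count was 45 (19 more positive) without Be(2)-C DMSO 1, 49 (19) without Be(2)-C DMSO 2, 84 (34) without IMR5-75 DMSO 2, 52 (21) without IMR5-75 EPZ 1 and 98 (52) without IMR5-75 EPZ 2. The count for both drugs was 1074 without Be(2)-C DMSO 1, 1156 without Be(2)-C DMSO 2 and 1130 without Be(2)-C DAC+EPZ 1. For both drugs the genes more negative in IMR5-75 numbered 303, 363 and 360 without these 3, 415 without IMR5-75 DMSO 1 and 286 without IMR5-75 DAC+EPZ 2. For DAC they numbered 61, 78 and 98 without Be(2)-C DMSO 1, DMSO 2 and DAC 1, and 104 and 105 without IMR5-75 DMSO 1 and DAC 1. The share of counts from RMRP and RPPH1, abundant short structured RNAs, was 2.84 ± 0.206% in DMSO, 3.04 ± 0.553% after DAC, 3.35 ± 0.131% after EPZ and 3.72 ± 0.0184% under both drugs in Be(2)-C (n = 2). In IMR5-75 it was 1.70 ± 0.314%, 2.60 ± 0.585%, 1.84 ± 0.214% and 3.07 ± 0.921%. Only both drugs raised it in each library of both lines.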

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

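The tests of difference between lines were planned, while the tests that weigh explanations and the leaving out of libraries for lists were chosen after the result was seen. The lists and genes of the next 6 paragraphs stand out because the change differed between the lines by a test of the difference itself (edgeR or camera, IMR5-75 minus Be(2)-C, log2). The 3 patterns after them were not chosen by that test, and the interaction was not compared between lines. The genes called numbered 988 for DAC, 190 for EPZ and 1766 for both drugs. List medians include fitted values of genes at 0 counts in a group, and the members called in the direction of the list stand beside them. A list can be called with few or no called members.

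After DAC the lists more positive in IMR5-75 and held with an estimated correlation were clustered protocadherin genes (2.87, 35 of 52), germline genes (1.818, 6 of 33), cancer-testis genes (1.311, 2 of 28), genes methylated in neuroblastoma (1.3, 9 of 26), p53 target genes (0.878, 21 of 36), interferon-stimulated genes (0.813, 4 of 36), mesenchymal-type genes (0.748, 12 of 40 and 2 more negative) and neuronal maturation genes (0.711, 14 of 43). More negative were DNA replication genes (-0.294, 1 of 44) and MYC and MYCN target genes (-0.193, 1 of 40). Lost with an estimated correlation were Schwann and glial markers (1.251, 0 of 9 with edgeR and DESeq2 and 1 at an unadjusted p under 0.05, adjusted p = 0.0537), EZH2-repressed neuroblastoma suppressors (1.018, 1 of 3, 0.0754), noradrenergic identity genes (0.52, 12 of 30, 0.0633) and antigen presentation genes (0.47, 3 of 16, 0.0764). The same held for cholesterol synthesis genes (0.226, 4 of 25, 0.0754), mitosis genes (-0.363, 5 of 40, 0.0754), DNA methylation and Polycomb machinery (-0.135, 1 of 38 and 1 more positive, 0.187), ATF4 and unfolded protein response genes (-0.225, 5 of 30, 0.475) and replication-dependent histone genes (median -0.059, mean 1.93, test upward, 18 of 57, 0.557). With 1 library left out, the germline genes called numbered 2 without Be(2)-C DMSO 2 or IMR5-75 DMSO 2 and 3 without Be(2)-C DMSO 1 or DAC 2. The mesenchymal-type genes numbered 7 without Be(2)-C DMSO 1, the cancer-testis genes 1 without Be(2)-C DMSO 2, and the antigen presentation genes 1 without Be(2)-C DMSO 1, Be(2)-C DAC 1 or IMR5-75 DMSO 2. The mesenchymal-type genes more negative numbered 1 without Be(2)-C DMSO 1, Be(2)-C DMSO 2 or IMR5-75 DAC 2. The DNA replication genes numbered 2 without Be(2)-C DAC 2 or IMR5-75 DAC 1, and without IMR5-75 DAC 2 the MYC and MYCN target genes numbered 3, the EZH2-repressed neuroblastoma suppressors 2 and the mitosis genes 8. The mitosis genes numbered 2 without any of the other libraries compared but Be(2)-C DAC 2. The ATF4 and unfolded protein response genes numbered 1 without Be(2)-C DAC 2, 2 without Be(2)-C DMSO 1 and 3 without Be(2)-C DMSO 2, IMR5-75 DMSO 1, DMSO 2 or DAC 2. The machinery genes more negative numbered 0 without Be(2)-C DMSO 1, Be(2)-C DAC 1 or IMR5-75 DAC 1, and those more positive 0 without Be(2)-C DMSO 1 or DMSO 2. With 1 library left out, calls ended for ATF4 and unfolded protein response genes (without Be(2)-C DAC 2 0.533, IMR5-75 DMSO 2 0.071, IMR5-75 DAC 2 0.057), histone genes (IMR5-75 DMSO 1 0.505) and Schwann and glial markers (IMR5-75 DMSO 2 0.0757). The DNA methylation and Polycomb machinery call ended without Be(2)-C DMSO 1 (0.106), Be(2)-C DAC 1 (0.0782), IMR5-75 DMSO 2 (0.0955), IMR5-75 DAC 1 (0.064) or IMR5-75 DAC 2 (0.057).

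After EPZ DNA replication genes (0.523, 11 of 44) held with an estimated correlation, while mitosis genes (0.542, 8 of 40, adjusted p = 0.0534), replication-dependent histone genes (0.748, 3 of 57, 0.309), cholesterol synthesis genes (0.382, 0 of 25 with edgeR, 1 with DESeq2 and 11 at an unadjusted p under 0.05, 0.0753) and ATF4 and unfolded protein response genes (-0.404, 2 of 30, 0.309) did not. These called members depended on single libraries. Without Be(2)-C DMSO 1, DMSO 2 and EPZ 1 the DNA replication genes numbered 1, 2 and 6, and without IMR5-75 DMSO 1, DMSO 2, EPZ 1 and EPZ 2 they numbered 3, 4, 2 and 3. The mitosis genes numbered 1 and 0 without Be(2)-C DMSO 1 and DMSO 2, and 2, 5, 2 and 3 without the same 4 libraries of IMR5-75. The histone genes numbered 0 without Be(2)-C DMSO 1, Be(2)-C DMSO 2 or IMR5-75 EPZ 1, 1 without Be(2)-C EPZ 2 or IMR5-75 DMSO 1, and 10 without Be(2)-C EPZ 1. The ATF4 and unfolded protein response genes numbered 0 without Be(2)-C DMSO 1, Be(2)-C DMSO 2, IMR5-75 DMSO 2, EPZ 1 or EPZ 2, 1 without Be(2)-C EPZ 1 and 5 without Be(2)-C EPZ 2. The cholesterol synthesis genes numbered 1 without Be(2)-C EPZ 2 or IMR5-75 DMSO 1.

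Under both drugs clustered protocadherin genes (2.68, 35 of 52), germline genes (2.733, 8 of 33), genes methylated in neuroblastoma (1.303, 9 of 26), cancer-testis genes (1.184, 2 of 28), Schwann and glial markers (1.134, 2 of 9), interferon-stimulated genes (0.915, 8 of 36), mesenchymal-type genes (0.882, 16 of 40 and 7 more negative), p53 target genes (0.739, 20 of 36) and MYC and MYCN target genes (-0.283, 6 of 40) held. Lost were neuronal maturation genes (0.702, 17 of 43 and 3 more negative, adjusted p = 0.056), antigen presentation genes (0.669, 4 of 16, 0.101), noradrenergic identity genes (0.448, 12 of 30 and 2 more negative, 0.105), cholesterol synthesis genes (0.209, 4 of 25, 0.0956), replication-dependent histone genes (0.081, mean 2.334, 20 of 57, 0.348) and mitosis genes (-0.484, 18 of 40, 0.0867). Lost too were ribosomal protein genes (-0.133, 0 of 74 with edgeR and DESeq2 and 1 at an unadjusted p under 0.05, 0.744) and DNA methylation and Polycomb machinery (-0.189, 4 of 38 and 1 more positive, 0.118). With 1 library left out, the mitosis genes numbered 11 without Be(2)-C DMSO 1, Be(2)-C DAC+EPZ 1, IMR5-75 DMSO 1 or IMR5-75 DAC+EPZ 1, 10 without Be(2)-C DMSO 2 and 9 without IMR5-75 DAC+EPZ 2. The MYC and MYCN target genes numbered 1 without Be(2)-C DMSO 1 or IMR5-75 DAC+EPZ 2, 2 without Be(2)-C DMSO 2, IMR5-75 DMSO 1 or IMR5-75 DAC+EPZ 1, and 3 without Be(2)-C DAC+EPZ 1. The mesenchymal-type genes numbered 10 without Be(2)-C DMSO 1 or DAC+EPZ 1, the interferon-stimulated genes 5 without Be(2)-C DMSO 2 or IMR5-75 DMSO 1, and the cholesterol synthesis genes 2 without IMR5-75 DMSO 1. The antigen presentation genes numbered 1 without Be(2)-C DMSO 1 and 2 without Be(2)-C DMSO 2, Be(2)-C DAC+EPZ 1 or IMR5-75 DMSO 2. The Schwann and glial markers numbered 0 without Be(2)-C DMSO 1 or IMR5-75 DMSO 2, and 1 without any other library compared but IMR5-75 DAC+EPZ 1. The machinery genes more negative numbered 0 without Be(2)-C DMSO 1 or IMR5-75 DAC+EPZ 2, 1 without IMR5-75 DMSO 1 and 2 without Be(2)-C DMSO 2, Be(2)-C DAC+EPZ 1 or IMR5-75 DMSO 2, and those more positive 0 without Be(2)-C DMSO 1 or DAC+EPZ 1. The noradrenergic identity genes more negative numbered 1 without IMR5-75 DMSO 1 and 0 without Be(2)-C DMSO 1, DMSO 2 or DAC+EPZ 2 or IMR5-75 DAC+EPZ 1 or DAC+EPZ 2. The machinery call ended without IMR5-75 DAC+EPZ 2 (0.0945), and the ribosomal protein genes call without Be(2)-C DMSO 2 (0.102), Be(2)-C DAC+EPZ 1 (0.604), IMR5-75 DMSO 2 (0.423) or IMR5-75 DAC+EPZ 1 (0.549).

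Of 260 tests of named genes, 88 showed a difference, and 52 of these stood with each of 8 libraries left out. After DAC these were HIST1H3J (6.774), HIST1H4I (5.999, 5.11 without IMR5-75 DMSO 2, and 0 DMSO counts left without IMR5-75 DMSO 1), HIST1H3C (5.37, 3 DMSO counts left without IMR5-75 DMSO 1), NEFH (4.142), VIP (3.913, 4.56 without IMR5-75 DMSO 2), PARP14 (3.171), SCG2 (2.882), PRPH (2.73), CDKN1A (2.558), CHGA (2.058), NT5E (2.028), CLU (1.954), BTG2 (1.428), TM7SF2 (1.411), STARD4 (1.359), SLC7A11 (-2.091), LDHA (-2.405) and H19 (-4.267). After EPZ they were FOS (3.359), PRPH (1.306), GINS2 (1.065), FN1 (-1.378) and SEL1L3 (-3.496). Under both drugs they were GDF15 (8.456, 7.85 without Be(2)-C DMSO 2), HIST1H3C (6.365, the same 3 counts left), HIST1H2BE (5.033), PCDH19 (3.58), SCG2 (3.343), PRPH (3.287), HIST1H2BI (2.893), CDKN1A (2.493), NEFM (2.409), CLU (2.117), LGALS3BP (1.524), STARD4 (1.469), CHGB (1.383), BTG2 (0.8), SNHG1 (-0.715), BUB1 (-0.762), KIF15 (-1.077), SPARC (-1.208), LDHA (-2.056), FN1 (-2.302) and H19 (-3.495). With a group at or under the floor, only an adjusted p is given: HIST1H1B 2.91e-11, HIST1H1D 4.37e-11 and PCDHB2 1.81e-10 after DAC, and HIST1H1B 2.67e-12, HIST1H1D 4.52e-12, TDRD1 1.04e-11, PCDHB2 8.5e-10 and WT1 0.00135 under both drugs.

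The other 36 lost the call with at least 1 library left out. Calls that ended without 1 library were, after DAC, TP53INP1 (1.105; Be(2)-C DMSO 2, adjusted p = 0.0567), PCDHB5 (2.899; Be(2)-C DMSO 2, 0.0833), KRT19 (adjusted p 0.00954; IMR5-75 DMSO 1, 0.647) and GABBR1 (adjusted p 0.00452; IMR5-75 DMSO 1, 0.0892), and after EPZ, F2R (adjusted p 0.0115; Be(2)-C DMSO 1, 0.152) and GRB10 (-2.466, Be(2)-C DMSO 1, 0.0967, and -3.05 without Be(2)-C DMSO 2). Under both drugs they were NTRK3 (-2.512, Be(2)-C DMSO 2, 0.0772, with 2 DMSO counts left without Be(2)-C DMSO 1), KRT19 (adjusted p 0.0021, IMR5-75 DMSO 1, 0.31) and TGFBI (adjusted p 0.00957, Be(2)-C DMSO 1, 0.302).

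Calls that ended without any single one of several libraries were, after DAC, TMEM117 (2.264, Be(2)-C DMSO 2, DAC 1 and IMR5-75 DMSO 1, DMSO 2, DAC 2, up to 0.246, with 1.55 without Be(2)-C DAC 1 and 1 DAC count left without DAC 2), AEN (0.722, Be(2)-C DMSO 2 and IMR5-75 DMSO 1, up to 0.0702), MKRN3 (-2.186, Be(2)-C DMSO 1, DMSO 2, DAC 1 and IMR5-75 DMSO 1, DMSO 2, DAC 1, DAC 2, up to 0.242), XKR5 (adjusted p 0.0449, Be(2)-C DMSO 1, DMSO 2, DAC 1 and IMR5-75 DMSO 1, DMSO 2, DAC 1, DAC 2, up to 0.192), PSME1 (0.587, Be(2)-C DMSO 1, DMSO 2, DAC 1 and IMR5-75 DMSO 1, DMSO 2, DAC 1, up to 0.207), KIF15 (-0.703, Be(2)-C DMSO 1, DMSO 2, DAC 1 and IMR5-75 DMSO 1, DMSO 2, DAC 1, up to 0.134), PHGDH (-1.097, Be(2)-C DAC 2 and IMR5-75 DAC 2, up to 0.0701), SLC7A5 (-0.813, Be(2)-C DMSO 1, DMSO 2, DAC 1, DAC 2 and IMR5-75 DMSO 1, DMSO 2, DAC 2, up to 0.204) and SNHG1 (-0.66, Be(2)-C DMSO 1, DAC 2 and IMR5-75 DMSO 1, DAC 1, up to 0.0903). After EPZ they were NUSAP1 (0.838, Be(2)-C DMSO 1, DMSO 2 and IMR5-75 EPZ 2, up to 0.0654), KIF20A (0.677, Be(2)-C DMSO 1, DMSO 2, EPZ 1 and IMR5-75 DMSO 1, DMSO 2, EPZ 1, EPZ 2, up to 0.166), CHAF1B (0.862, Be(2)-C DMSO 1, DMSO 2, EPZ 2 and IMR5-75 DMSO 1, DMSO 2, EPZ 1, EPZ 2, up to 0.11), TP53I3 (0.871, Be(2)-C DMSO 1 and IMR5-75 DMSO 2, EPZ 1, up to 0.0726) and CD9 (1.046, Be(2)-C DMSO 1, DMSO 2 and IMR5-75 DMSO 2, up to 0.0779). Under both drugs they were SLC18A2 (-0.861, Be(2)-C DMSO 1, DMSO 2, DAC+EPZ 2 and IMR5-75 DMSO 1, DAC+EPZ 1, DAC+EPZ 2, up to 0.119), MKRN3 (-2.048, any of the 8 libraries, up to 0.214), PCDHB5 (2.181, Be(2)-C DMSO 2, DAC+EPZ 1 and IMR5-75 DMSO 1, DMSO 2, up to 0.184), LCP1 (1.619, Be(2)-C DMSO 1 and IMR5-75 DMSO 2, DAC+EPZ 1, up to 0.16, with 3 DMSO counts left without IMR5-75 DMSO 1), NEAT1 (0.738, Be(2)-C DMSO 1, DMSO 2, DAC+EPZ 1 and IMR5-75 DMSO 1, DMSO 2, DAC+EPZ 1, up to 0.205), DNMT3A (-0.576, Be(2)-C DMSO 1 and IMR5-75 DMSO 1, DAC+EPZ 2, up to 0.111), TKTL1 (adjusted p 0.037, Be(2)-C DMSO 1, DMSO 2, DAC+EPZ 1 and IMR5-75 DMSO 1, DMSO 2, up to 0.242), KIAA0125 (adjusted p 0.0351, Be(2)-C DMSO 1, DMSO 2, DAC+EPZ 2 and IMR5-75 DMSO 1, DAC+EPZ 1, DAC+EPZ 2, up to 0.156), ZNF630 (adjusted p 0.0485, Be(2)-C DMSO 1, DMSO 2, DAC+EPZ 1, DAC+EPZ 2 and IMR5-75 DMSO 1, DAC+EPZ 1, DAC+EPZ 2, up to 0.246), ERAP1 (0.704, Be(2)-C DMSO 1, DMSO 2, DAC+EPZ 1, DAC+EPZ 2 and IMR5-75 DMSO 2, DAC+EPZ 1, up to 0.149), NGFR (-1.614, Be(2)-C DMSO 1, DMSO 2, DAC+EPZ 2 and IMR5-75 DMSO 2, DAC+EPZ 1, DAC+EPZ 2, up to 0.421, with -2.25 and -0.61 without IMR5-75 DMSO 1 and DMSO 2), SLC19A1 (-0.711, Be(2)-C DMSO 1, DAC+EPZ 2 and IMR5-75 DAC+EPZ 1, DAC+EPZ 2, up to 0.0974) and MTHFD2 (-0.524, Be(2)-C DMSO 1, DMSO 2, DAC+EPZ 1 and IMR5-75 DMSO 1, DMSO 2, DAC+EPZ 1, DAC+EPZ 2, up to 0.205).

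The first pattern concerned 62 genes with at most 3 counts in IMR5-75 DMSO and at least 20 CPM in Be(2)-C DMSO, of which 41 were called higher after DAC in IMR5-75. Carry-over of Be(2)-C RNA or reads argues for 1 shared percentage of the Be(2)-C level, but 33 genes had intervals more than 2-fold away from the pooled share of 3.91%, with a range from 0 to 40.3%. Genes picked for a low in DMSO tend to rise elsewhere, and 53 had more counts after EPZ than in DMSO (376 against 91 in sum, and 5643 after DAC). A chance low as the whole cause is argued against by 39 genes called higher under both drugs than after EPZ, 38 of them among the 41, in libraries that did not pick them. It stays open for the other 3, FGF14 (13 counts after EPZ, 14 after DAC), ZNF331 (17 and 21) and ZNF680 (13 and 18). Loss of DNA methylation at the 41 genes may explain their counts and stays open, since methylation was not analysed here.

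The second pattern was the lower histone counts in Be(2)-C. Reads shared between near-identical histone genes would leave the summed level as it was, but it was at most 50.1% of DMSO (20280 ± 1180 CPM to 10170 ± 828 after DAC, n = 2). Lower recovery of RNAs without a poly(A) tail is argued against by the small structured and nuclear RNAs, whose lowest lower quartile over the treatments was -0.179. Fewer cells in S phase remain a candidate explanation, as at least 30 of 44 DNA replication genes were called lower in each treatment.

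The third pattern was the 39 genes below the sum of the single-drug changes in Be(2)-C, with a median of -2.14. A single deviating library is argued against as the cause of all these calls, since at least 16 genes were called below the sum with 1 library left out. The fewest were 16 without DMSO 1, and there were 18 without DAC 2 and 24 without DAC+EPZ 1 or DAC+EPZ 2. These 16 genes were called with each library left out. The calls of the other 23 ended without at least 1 library as the spread widened (median SE 0.257, and 0.269 to 0.302 with 1 left out), but each value stayed below 0 by over 2 SE and at no less than 0.681 of its size. Their median was -1.465, and -1.189 without DAC 2 to -1.595 without DMSO 2. These genes were picked for low values in the same libraries, so their values cannot test a single library as the cause. Culture stress differing between cultures may have contributed and stays open, with no runs labelled. GDF15, INHBE, HMOX1 and FAM129A were higher in DAC 2 than DAC 1. The ATF4 list's median interaction was -0.712 in Be(2)-C (26 of 30 below 0) and 0.163 in IMR5-75 (8 of 30), a difference not tested.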

How the results depend on the processing

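Leaving out libraries was chosen after seeing the data for the gene lists, and the other alternatives were planned. Fewer libraries leave fewer residual degrees of freedom. Otherwise the cause was not tested where a result moved. All alternatives that were planned were run, except that DESeq2 gave no adjusted p for 2 named gene settings. The depth limits genes near the floor of 3 counts, and 1.5-fold changes were recovered in 22.4 to 44% of simulated cases. Of 353 called results of named genes, DESeq2 size factors kept 352 calls and no filter 353, DESeq2 kept 337 of 351 and each line alone 294 of 311, and 95 lost the call with at least 1 library left out. Of 134 called list results, an estimated correlation kept 78 and fry 116, and 21 lost the call with at least 1 library left out. With each library left out, 658 of 700 called list settings kept the call and 3 reversed, all of them ribosomal protein genes. Counts of 1 or 2 called members of a list often moved by 1 or 2 with a library left out, so nothing is concluded from them.

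By replicate number, 6 pairs in Be(2)-C correlated from -0.39 to 0.034 and 6 in IMR5-75 from -0.459 to 0.397 (2 above 0.1). The numbers do not pair the libraries, but a shared batch stays open. With a replicate term, 330 of 353 called named genes and 132 of 134 called lists kept their calls. The genes called then numbered 703 (270 lower) for DAC in Be(2)-C, 188 (20 lower) for EPZ in IMR5-75, 124 (34 lower) for both drugs against DAC in IMR5-75 and 98 (41 more positive) for the EPZ difference between lines. The lower genes of both drugs against DAC in Be(2)-C numbered 203, the more negative genes of the DAC difference 110, and the Polycomb-bound developmental regulators of the DAC difference between lines reversed (adjusted p = 0.983). Without a low-count filter the counts were 109 (28 above the sum) for the interaction in Be(2)-C, 740 (233 lower) for EPZ in IMR5-75, 541 (408 higher) for both drugs against DAC in IMR5-75, 84 (47 above the sum) for the interaction in IMR5-75 and 425 (217 more positive) for the EPZ difference between lines. DESeq2 gave 14 (5 above the sum) for the interaction in IMR5-75, 292 (153 more positive) for the EPZ difference between lines and 86 lower genes for EPZ in IMR5-75. IMR5-75 fitted alone gave 164 (48 lower) for both drugs against DAC, 29 lower genes for EPZ and 1 for the interaction. The 2 genes above the sum in Be(2)-C lost their calls with a replicate term and with Be(2)-C fitted alone. With fry, germline genes of EPZ in Be(2)-C (adjusted p = 0.848), small structured and nuclear RNAs of EPZ in IMR5-75 (0.984), epithelial markers of the DAC difference (0.972) and MYC and MYCN target genes of the EPZ difference (0.914) reversed, none of them called.

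With 1 library left out, the counts for Be(2)-C ranged from 297 to 583 for DAC, 571 to 1263 for EPZ, 2100 to 2648 for both drugs, 323 to 443 for both against DAC, 283 to 550 for both against EPZ and 16 to 49 for the interaction. In IMR5-75 they ranged from 32 to 344 for EPZ, 48 to 218 for both against DAC, 3728 to 4822 for both against EPZ and 1 to 10 for the interaction, and between lines from 45 to 213 for EPZ and 1074 to 1541 for both drugs. DNMT3B, called nowhere, changed sign, from -0.031 to 0.118 for DAC, -0.043 to 0.164 for both drugs in Be(2)-C, -0.155 to 0.189 for DAC, -0.213 to 0.140 for EPZ and -0.335 to 0.006 for both in IMR5-75, as did EZH1 for EPZ in Be(2)-C, from -0.027 to 0.150.

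Lists that changed direction with a library left out had these ranges of adjusted p. For DAC in Be(2)-C they were ribosomal protein genes 4.22e-08 to 0.55, ATF4 and unfolded protein response genes 1.43e-05 to 0.47 and small structured and nuclear RNAs 0.0217 to 0.534. For EPZ in Be(2)-C they were germline genes 0.769 to 0.944, Polycomb-bound developmental regulators 0.545 to 0.999, genes methylated in neuroblastoma 0.767 to 0.999, HOX genes 0.084 to 0.881 and noradrenergic identity genes 0.0222 to 0.896, and for both drugs ribosomal protein genes 0.0344 to 0.601. For EPZ in IMR5-75 they were cholesterol synthesis genes 0.115 to 0.74, ribosomal protein genes 0.00758 to 0.74 and small structured and nuclear RNAs 0.27 to 0.717, and for both drugs ribosomal protein genes 5.16e-05 to 0.597 and small structured and nuclear RNAs 0.0637 to 0.94. For the DAC difference between lines they were epithelial markers 0.345 to 0.98, small structured and nuclear RNAs 0.102 to 0.87, Polycomb-bound developmental regulators 0.769 to 0.963, ribosomal protein genes 0.00113 to 0.766 and imprinted genes 0.632 to 0.949. For the EPZ difference they were HOX genes 0.321 to 0.999, DNA methylation and Polycomb machinery 0.568 to 0.999, MYC and MYCN target genes 0.632 to 0.992, EZH2-repressed neuroblastoma suppressors 0.571 to 0.947, neuronal maturation genes 0.307 to 0.879, imprinted genes 0.618 to 0.999, cancer-testis genes 0.632 to 0.999, interferon-stimulated genes 0.568 to 0.99 and epithelial markers 0.632 to 0.999. For the difference under both drugs they were small structured and nuclear RNAs 0.176 to 0.982, HOX genes 0.634 to 0.982, epithelial markers 0.426 to 0.982, DNA replication genes 0.483 to 0.982 and ribosomal protein genes 1.97e-06 to 0.604.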

Other observations

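All tests in this part were chosen after the result was seen. The histone genes of IMR5-75 after DAC were split by their level in DMSO. Of 13 at or under the floor of 3 counts over the DMSO group 11 were called higher, and of 44 above it 8 were called higher and 34 lower. A gene with at most 3 counts can hardly be called lower, so the split itself cannot show that a low level in DMSO goes with a rise. Of the 8 genes, 7 held 5 to 25 counts over the DMSO group, and HIST1H2AJ stood at 15 CPM. In Be(2)-C DMSO the 13 genes had a median of 213 CPM and ranged from 0.0912 CPM (HIST1H4F) to 1210 CPM (HIST1H1B). Whether low copies may have been reactivated is left open, and histone copies can share reads.

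MYCN and its neighbours were compared to ask whether the whole amplified segment had lower counts after DAC in IMR5-75. In DMSO, DDX1 stood at 13550 CPM in IMR5-75 against 404 CPM in Be(2)-C, and NBAS at 8132 CPM against 217 CPM. MYCN itself stood at 1872 CPM in IMR5-75 and 5239 CPM in Be(2)-C. Of the 2 neighbours at or above 1000 CPM, 1 was called lower after DAC: DDX1 fell by 0.77 ± 0.12, while NBAS differed by -0.10 ± 0.13. MYCNOS, at 128 CPM in IMR5-75 DMSO, fell by 0.74 ± 0.15 and MYCN by 0.52 ± 0.14, and the MYCN call ended without DMSO 2 or DAC 2, at adjusted p up to 0.113. Only NBAS, of these 4 genes, argues against a decrease of the whole segment, and a decrease of the part with DDX1, MYCNOS and MYCN may remain.

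Genes named ZNF, mostly zinc finger transcription factors, were asked to rise more often than other genes after DAC in IMR5-75. Of 506 tested, 23.5% were called higher against 19.8% of other genes (odds ratio 1.25, Fisher's exact p = 0.0416, adjusted p = 0.0832 over the 6 treatments). The odds ratio was 0.116 after EPZ and 0.768 under both drugs in IMR5-75 (adjusted p = 0.0224 and 0.0519). In Be(2)-C it was 1.01 after DAC, 0.837 after EPZ and 0.93 under both drugs (adjusted p = 0.905, 0.723 and 0.769), so the rise was not seen in the other treatments with DAC and the hypothesis stays open.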
